A study of Mus musculus with 9 samples.

How the data were processed

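HiChIP joins chromatin conformation capture to immunoprecipitation, so that read pairs report contacts between distant DNA segments held near a chosen protein or histone mark. Here it was done on sorted CD4+ CD8+ thymocytes, the double-positive stage of T cell development, from mouse strains C57BL/6J (BL6) and NOD/ShiLtJ (NOD) and from an F1 cross of NOD/ShiLtJ with C57BL/6, whose substrain the labels do not give. The antibodies recognised Smc1, a cohesin subunit, or H3K27ac, a histone mark of active promoters and enhancers. The 9 libraries fell into 5 groups by the strain and antibody fields of the labels. The titles of the 4 H3K27ac samples name Smc1, against their antibody field, while the names of their deposited tables carry the histone mark. The antibody field was followed, so every H3K27ac value and antibody comparison rests on that field. The labels call the 2 Smc1 libraries of each strain technical replicates of 1 biological replicate, and the 2 H3K27ac libraries of each strain biological replicates. P-values for Smc1 therefore measure spread between libraries that may be technical. The F1 library had no replicate.

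The values used were counts of read pairs per listed interaction, deposited by the authors without normalization, per the file headers. The tables also gave reads per anchor as counts, per the file headers, with a p-value and a q-value deposited for every interaction. Each of the 10 tables listed only interactions within a chromosome with at least 2 read pairs and a q-value up to 0.05, as checked on the values. A pair missing from a table was thus under that limit and not measured as 0, and no fold is given against a group with no listed interaction. In the sums and in all fits such a pair nevertheless counted as 0. The submitters' processing notes name HiC-Pro, Juicer 1.7.6 and MACS, with no role for each, and the build GRCm38. Per the names the authors gave the deposited tables, the NOD tables were made on the NOD genome and their coordinates shifted to the BL6 reference. The F1 library was deposited in both forms. BL6 and NOD libraries thus differ in mapping genome as well as in strain.

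Interactions on chromosomes 1 to 19 and X with anchor midpoints at least 10 kb apart were kept. Read pairs were summed per protein-coding gene over interactions with an anchor within 5 kb of either end of the gene, each interaction counting once per gene. The gene table used here (GRCm38.p6, 21627 genes) carries no strand, so transcription start sites could not be placed. Windows around both gene ends contain the start site but also the other end, and they replaced the start-site windows planned before the data were examined. Neighbouring and overlapping genes share interactions. Read pairs were also summed per pair of 25 kb bins. Python 3.11.15 with pandas 2.3.3 was used for these sums.

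NOD and BL6 libraries were compared within each antibody with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM normalization, robust dispersion and the default expression filter. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. An interaction term over 8 libraries tested whether the strain difference differed between antibodies, and H3K27ac was compared with Smc1 in BL6. The 16 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01, with an estimated correlation, and with fry. List medians include fitted changes of genes with no listed interaction in 1 group. The F1 library was described without a test, as the log2 ratio of CPM on the NOD genome to CPM on the BL6 genome with 5 CPM added to each. A gene was said to differ between genomes when that ratio exceeded 1.5-fold either way.

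The rule for named genes, also fixed before the data were examined, took genes with an adjusted p under 0.05, separated libraries and a mean of at least 50 read pairs in the higher group. It took up to 10 rises and 10 falls by size, passed over clone-type names, and kept the smallest p among genes within 100 kb. It added list members with an adjusted p under 0.05 and the 10 genes with the highest mean CPM per antibody. For bin pairs it took up to 5 rises and 5 falls with at least 20 read pairs, and for the F1 and antibody comparisons 5 each way. Because start sites were not placed, distances between genes were taken between gene bodies. Genes outside this rule are named as chosen after their values were seen.

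The fits were tested on simulated counts drawn from the real means, depths and dispersions, with known folds in up to 200 features. For Smc1 genes (17146 tested), 2% of 2-fold, 25% of 4-fold, 70% of 8-fold and 88% of 16-fold changes were called, with 1 unchanged gene called. For H3K27ac genes (9898 tested), 25% of 16-fold changes and 0% of 8-fold changes were called. Of 16-fold changes, 2.70% of 37 were called for Smc1 bin pairs (3372 tested) and 0% of only 6 for H3K27ac bin pairs (178 tested). The shares of 16-fold changes called were 16.3% for the interaction (17130 tested) and 71.4% for H3K27ac against Smc1 (16289 tested). A simulated 2-fold rise of 1 whole list was called in each antibody, with 0 of 15 other lists called. Genes were drawn independently there, so false calls of lists whose members vary together were not covered. In the data the estimated correlation reached 0.59 for MHC region genes in Smc1. In these simulations, the tests of single genes and bin pairs mostly missed differences of 4-fold or less. Alternatives covered normalization with DESeq2 size factors, the DESeq2 1.42.0 test, filters, window and bin sizes, interaction spans, the joint fit, the replicate block and each library left out. Further alternatives chosen after seeing the data were normalization within each chromosome, whole gene spans, 25 kb bins in place of genes, at least 3 read pairs, a q-value up to 0.01, and for lists each library left out.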

Results

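Contacts held near cohesin (Smc1) or near H3K27ac were listed for double-positive thymocytes of BL6 mice, of NOD mice, a strain that develops autoimmune diabetes spontaneously, and of an F1 cross of NOD and C57BL/6. The Smc1 tables held 1899789 and 2620662 used read pairs in BL6 libraries 1 and 2 and 1663253 and 1484374 in NOD libraries 1 and 2. The F1 library held 765188 on the BL6 genome and 791770 on the NOD genome. The H3K27ac libraries were shallower, with 440901 and 1203808 used read pairs in BL6 and 380953 and 497689 in NOD. Between 59.6% and 73.5% of the used interactions rested on 2 read pairs. Chromosome X carried between 3 and 62 listed interactions per table.

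The first comparison asked which genes differed between NOD and BL6 in cohesin-associated contacts. Contacts of 17 genes rose in NOD and 0 fell, of 17792 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and these 17 lay at 13 loci more than 100 kb apart. The lymphocyte lectin receptor genes Klra1 and Klra4, of the Ly49 family of natural killer cell receptors on chromosome 6, were among them. Klra1 (130363918 to 130386874) went from 3.91 ± 0.620 CPM in BL6 to 562 ± 460 CPM in NOD (SD of 2 technical libraries of 1 biological replicate per strain), a log2 fold change of 7.10 ± 0.79 (SE, edgeR adjusted p = 0.0155). Klra4 (130043730 to 130067301) rose by a log2 fold change of 5.62 ± 0.69 (edgeR adjusted p = 0.0252). With 1 biological replicate per strain, these adjusted p-values measure technical spread, not variation between animals. Ly49 genes are closely similar copies, so their read pairs cannot be assigned to single members with certainty.

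Away from the Ly49 cluster, Mrgpra3 on chromosome 7, which encodes an itch receptor of sensory neurons, rose by 3.97 ± 0.46 on the log2 scale (edgeR adjusted p = 0.0155). The zinc finger gene Zfp988 on chromosome 4 rose by 4.04 ± 0.53 (edgeR adjusted p = 0.0294), and Tmem267 on chromosome 13 rose by 3.01 ± 0.41 (edgeR adjusted p = 0.0329). Sfi1 on chromosome 11 (3131850 to 3203347), which encodes a centrosomal protein, had 16 and 7 read pairs in the BL6 libraries against 910 and 1606 in the NOD libraries (edgeR adjusted p = 0.0155). Its neighbours Eif4enif1 and Gm51877 share interactions with it and were also called. Ifi203 on chromosome 1, an interferon-inducible gene, had no listed interaction in either BL6 library and 42 and 61 read pairs in the NOD libraries (edgeR adjusted p = 0.0409). Mroh2a on chromosome 1 and the double homeobox gene Duxf3 on chromosome 10 likewise had no listed interaction in BL6, with 78 and 67 and with 57 and 69 read pairs in NOD (edgeR adjusted p = 0.0155 and 0.0230). Of the 17 genes, 11 differed by over 1.5-fold between the genomes on which the single F1 library was mapped, and 6 did not. Sfi1, Mroh2a and Duxf3 had 3767, 136 and 146 F1 read pairs on the NOD genome and 0 on the BL6 genome, and Tmem267 had 431 and 216. Klra1 had 162 and 146, Klra4 100 and 85, Zfp988 291 and 230, Mrgpra3 74 and 56, and Ifi203 27 and 21 in the same order.

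**Figure D1:**
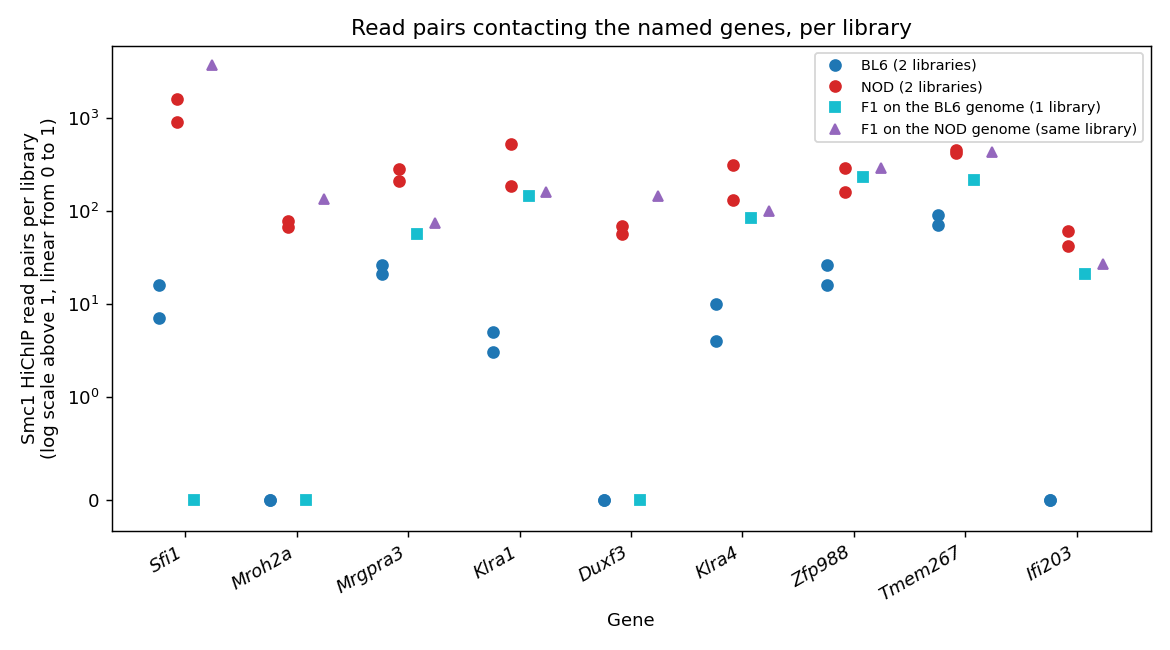
Smc1 read pairs per library (vertical axis, log scale above 1) for the 9 genes named by the rule (horizontal axis); circles are the BL6 and NOD libraries, squares and triangles the F1 library on the BL6 and on the NOD genome. Every NOD library lies above both BL6 libraries, and the F1 squares of Sfi1, Mroh2a and Duxf3 lie at 0.

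At an unadjusted p under 0.05, 657 genes passed, and DESeq2 called 55. The call count went to 0 without BL6 library 1 and also without BL6 library 2, to 601 (98 up, 503 down) without NOD library 1, and to 59 without NOD library 2, and all 17 genes kept a positive fold change in each of these. Leaving out the genes that differed between genomes in F1 removed 11 of the 17 by construction and left 3 called, while Klra4 (5.62, edgeR adjusted p = 0.0534), Zfp988 (4.04, edgeR adjusted p = 0.0552) and Ifi203 (edgeR adjusted p = 0.0821) missed the threshold.

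The genes of the strain-polymorphic families, a list of Ly49, interferon-inducible and related clusters known to vary between strains, stood higher in NOD as a group (camera adjusted p = 1.7e-06, adjusted p = 0.53 with an estimated correlation). The estimated correlation of this list was 0.0098, near the preset 0.01, so the larger adjusted p did not come from a higher correlation. Of 54 members tested, 37 had positive and 17 negative fold changes, with a median of 0.40. Over all genes 3 rose (Klra1, Klra4 and Ifi203), and 12 rose and 0 fell when adjusted over the list alone. The MHC region genes, which include antigen-presentation genes on chromosome 17, stood lower in NOD (camera adjusted p = 0.00917, adjusted p = 0.95 with an estimated correlation). None of their 30 tested members passed over all genes or adjusted over the list alone, 19 had negative and 11 positive fold changes, and the median was -0.49. The MHC call was lost without BL6 library 1 (camera adjusted p = 0.33), and its direction turned positive without NOD library 2 (camera adjusted p = 0.36). That library had 2.50% of its interactions on chromosome 17 against 3.75% to 4.11% in the other Smc1 libraries of both strains. With 1 gene kept per 100 kb, which left 20 and 5 members, neither list passed (camera adjusted p = 0.14 and 0.26). Neither passed with fry on all tested genes (fry adjusted p = 0.43 and 0.97 in the same order).

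With all libraries, genes tied to the thymocyte itself or to type 1 diabetes did not pass as groups. Of 59 type 1 diabetes and Idd candidate genes, 33 had positive and 26 negative fold changes, with a median of 0.07 (camera adjusted p = 0.74), and 0 passed either adjustment. The medians were 0.11 for 53 T cell receptor signalling genes, 0.02 for 57 thymocyte transcription factors, 0.17 for 43 double-positive stage genes, and -0.01 for 35 selection and apoptosis genes, and 0 members of each passed. Among 26 chemokine and migration receptors, 1 gene fell when adjusted over the list alone. That was Ccr6, chosen after its values were seen, which went from 67.9 ± 15.9 to 1.27 ± 1.79 CPM (SD of 2 technical libraries of 1 biological replicate per strain; edgeR adjusted p = 0.12 over all genes). Cytokines and receptors had a median of 0.07 and cohesin and CTCF genes -0.11. Medians of the marker lists of other cells were 0.22 for B cells, -0.07 for mature T cells, -0.09 for myeloid and dendritic cells, 0.14 for natural killer cells, -0.39 for erythroid cells and 0.20 for thymic epithelium. None of these lists passed with camera on all libraries. The fits below used the preset correlation of 0.01. On all libraries the estimated correlation was 0.44 for double-positive stage genes and 0.25 for T cell receptor signalling. Without NOD library 2, double-positive stage genes (camera adjusted p = 4.6e-05), T cell receptor signalling (camera adjusted p = 0.0030) and type 1 diabetes and Idd candidates (camera adjusted p = 0.0377) passed as higher in NOD. Without NOD library 1, double-positive stage genes (camera adjusted p = 0.0373), T cell receptor signalling (camera adjusted p = 0.0408) and thymocyte transcription factors (camera adjusted p = 0.0406) passed as lower in NOD.

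For contacts at H3K27ac, 0 of 12074 genes passed with edgeR (smallest adjusted p = 1.00), with 94 at an unadjusted p under 0.05 and 24 called by DESeq2. The count was 16 without BL6 library 2. In these separate libraries, all 17 genes raised in Smc1 had more CPM in both NOD libraries than in both BL6 libraries. That order held for 11.7% of the genes tested, and chance alone gives 16.7%. The H3K27ac NOD tables were also made on the NOD genome, so this order cannot tell strain from mapping. The 17 genes lay at 13 loci, and A530032D15Rik, Gm4981 and Ifi203 were not among the 12074 genes tested. Klra1 had no listed interaction in either BL6 library and 109 and 67 read pairs in NOD, and Sfi1 had 0 and 12 against 567 and 512. The strain-polymorphic families again stood higher in NOD (27 tested, camera adjusted p = 5.5e-09, adjusted p = 1.00 with an estimated correlation, fry adjusted p = 0.74). Of these, 0 rose over all genes and 8 rose adjusted over the list alone, among them Klra1, Klra7, Klra9 and Ifi202b. The group call held with 1 gene kept per 100 kb, which left 9 members (camera adjusted p = 2.6e-07). That group call was lost without BL6 library 2 (camera adjusted p = 0.32) and without NOD library 1 (camera adjusted p = 0.50), where the MHC region genes passed instead, as higher in NOD (camera adjusted p = 0.0019), opposite to their direction in Smc1. The MHC direction was lower in NOD without BL6 library 1 (camera adjusted p = 0.55) and without NOD library 2 (camera adjusted p = 0.17). Chromosome 17 held 1.68% and 1.26% of the interactions of H3K27ac BL6 1 and NOD 1, against 4.82% and 4.80% in BL6 2 and NOD 2. The other 15 lists did not pass, with medians of -0.05 for type 1 diabetes and Idd candidates, -0.05 for T cell receptor signalling, 0.22 for MHC region genes, -0.09 for thymocyte transcription factors, -0.14 for double-positive stage genes, -0.05 for selection and apoptosis, 0.01 for chemokine and migration receptors, -0.04 for cytokines and receptors and 0.02 for cohesin and CTCF genes. The marker lists had medians of 0.00 for B cells, 0.03 for mature T cells, -0.04 for myeloid and dendritic cells, -0.01 for natural killer cells, 0.15 for erythroid cells and 0.07 for thymic epithelium, and 0 members of these 15 lists passed either adjustment.

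The H3K27ac libraries resembled each other by replicate number and not by strain. Across genes, which are not independent replicates, r was 0.471 between BL6 1 and NOD 1 and 0.497 between BL6 2 and NOD 2, against 0.0550 within BL6 and 0.0311 within NOD. In Smc1, r was 0.664 within BL6, 0.490 within NOD, and 0.438 to 0.664 between strains. Chromosome 19 carried 0.799% and 0.537% of the interactions of H3K27ac BL6 1 and NOD 1, against 2.93% and 2.53% in BL6 2 and NOD 2. Each number held 1 library per strain, too few for a test within that number alone.

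**Figure D2:**
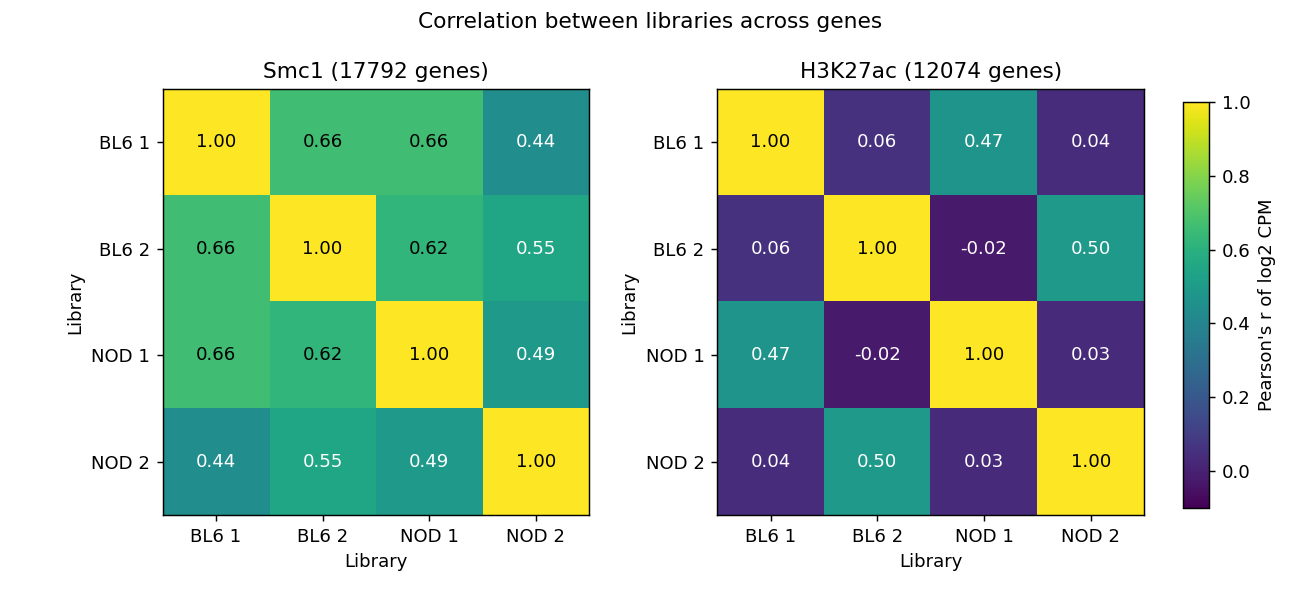
Pearson's r of log2 CPM across genes between libraries of the same antibody, with the 4 libraries of each antibody on both axes and the colour scale giving r. In H3K27ac the libraries that share a number (0.47 and 0.50) exceed those that share a strain (0.06 and 0.03).

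**Figure D3:**
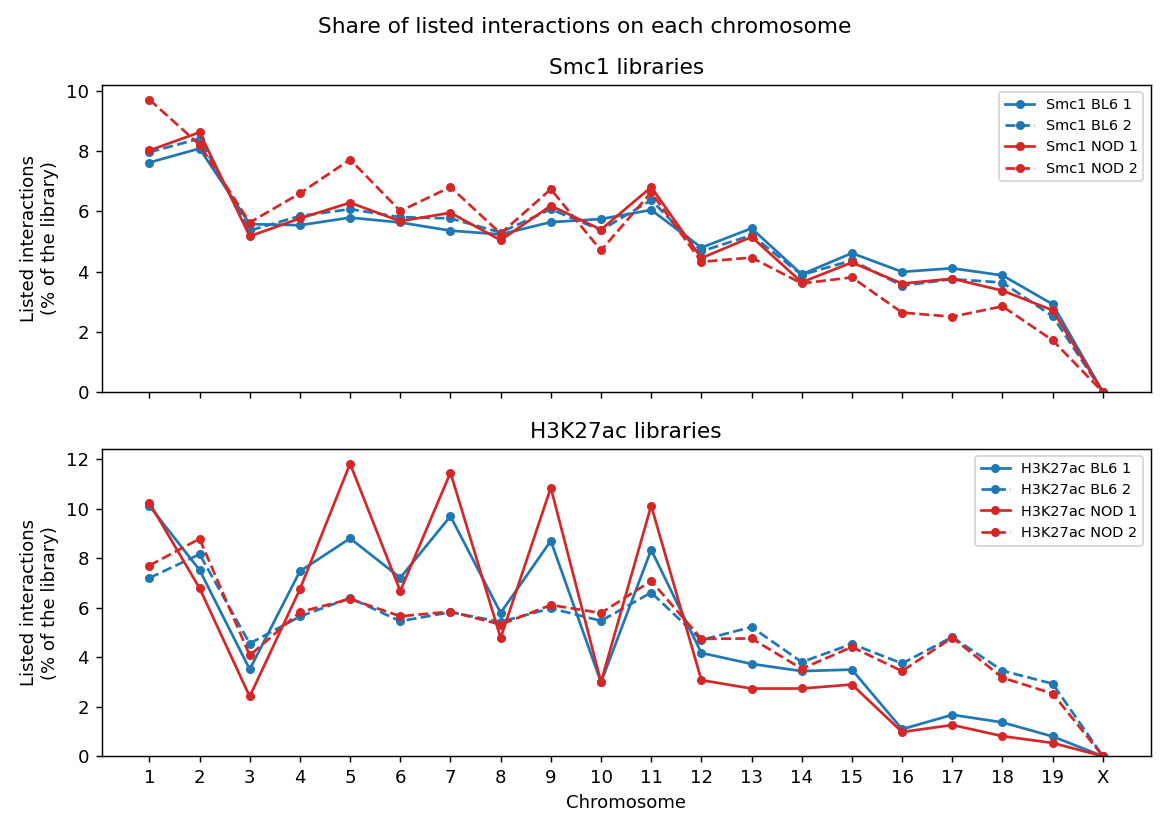
Percentage of each library's listed interactions (vertical axis) on each chromosome (horizontal axis), blue for BL6 and red for NOD, solid for library 1 and dashed for library 2. H3K27ac libraries 1 of both strains lie below libraries 2 on chromosomes 16 to 19.

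Pairs of 25 kb bins located the contacts themselves. In H3K27ac, 10 of 385 bin pairs rose in NOD and 0 fell (edgeR), and 6 of them lay within chromosome 11 between 3125001 and 3200000, at Sfi1. The pair 3150001 to 3175000 with 3175001 to 3200000 had 933 and 1064 read pairs in the NOD libraries (edgeR adjusted p = 3.6e-04), and its BL6 libraries had no listed interaction. All 10 called pairs had no listed interaction in BL6, and 8 had none in F1 on the BL6 genome. The count was 0 without either NOD library, 23 without BL6 library 2, and 0 with 50 kb bins. In Smc1, 0 of 5673 bin pairs passed with edgeR, 285 had an unadjusted p under 0.05, and DESeq2 called 143. The Sfi1 pair 3150001 to 3175000 with 3175001 to 3200000, which missed the threshold in Smc1, had 2350 and 3461 read pairs in the NOD libraries and no listed interaction in BL6 (edgeR adjusted p = 0.13). The edgeR count was 50 without BL6 library 1 and 61 without BL6 library 2.

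The strain difference itself did not differ detectably between antibodies. The interaction term passed for 0 of 17825 genes with edgeR, the only tool run for it, and 323 had an unadjusted p under 0.05. Within BL6, H3K27ac against Smc1 gave 0 of 17162 genes with edgeR (smallest adjusted p = 0.927), 850 at an unadjusted p under 0.05, and 4 with DESeq2. Among the smallest p-values, chosen after they were seen, the T cell surface receptor gene Cd6 had 491 and 320.1 CPM in H3K27ac and 36.3 and 11.5 CPM in Smc1 (log2 fold change 4.09 ± 0.76, edgeR adjusted p = 0.927). The call count depended on single H3K27ac libraries: it was 582 without BL6 1 and 3848 without BL6 2.

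The F1 library was read on both genomes, with 1083 genes holding at least 50 read pairs on the higher genome. Of these, 34 were over 1.5-fold higher on the NOD genome and 15 on the BL6 genome, together 4.52% (exact 95% interval 3.37% to 5.94%, counting error only). The balance turned with a minimum of 20 read pairs, with 227 genes higher on the NOD genome and 248 on the BL6 genome, and was 27 against 2 with interactions of at least 3 read pairs. Among genes the naming rule allows, which passes over clone-type names and neighbours within 100 kb, the largest ratios towards the NOD genome were at Sfi1, Sp140, Duxf3, Mroh2a and Klra3. Sp140, a nuclear body gene of lymphocytes, had 263 read pairs on the NOD genome and 0 on the BL6 genome. By the same rule, towards the BL6 genome they were at Gigyf2 (18 against 54 read pairs), Cacna1g (27 against 73), Ppp1r3b (25 against 55), Nr2c1 (30 against 58) and Zfp84 (31 against 56). Across 1080 genes, the F1 ratio correlated with the parental log2 fold change by Pearson's r of 0.611 and Spearman's rho of 0.0990, a relation across genes that are not independent. The tables shared 90.5% of the pairs of 25 kb bins of the smaller one, so the library was not divided by allele.

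Genes with the most contacts included T cell genes that did not pass the test between strains. In Smc1, Bcl11b, required for T cell commitment, had 454 ± 81.1 CPM in BL6 and 440.0 ± 210.4 in NOD (SD of 2 technical libraries of 1 biological replicate per strain), and the repressor gene Bcl6 had 394 ± 210.1 and 417 ± 227. The rest of the highest 10 were Ppil6, Tg, Galnt2, Eif4enif1, Gm51877, Sfi1, Gm42346 and Tmem267, of which the last 5 were called. In H3K27ac, Bcl11b had 470.1 ± 90.1 and 580 ± 297 CPM (SD, n = 2 each), the T cell surface receptor gene Cd6 454 ± 129 and 542 ± 252, Il21r 532 ± 470 and 399 ± 34.8, and Ctcf 730.1 ± 808 and 472 ± 57.3. Ripor1, Carmil2, Sfi1, Eif4enif1, Gm51877 and Tmem267 completed that list, and none passed in H3K27ac.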

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

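The tests of mapping, library depth, chromosome representation, label swaps and piled-up reads at genes that differ between genomes in F1 were chosen only after the results were seen. The test of piled-up reads at the other genes was fixed before its values were seen.

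Pairs under 10 kb, which no comparison used, were listed in tables of both strains. At 3 loci chosen by hand, without a search of the genome, NOD libraries listed them and no BL6 library did. On chromosome 2, between anchors at 98661815 to 98664406 and 98665730 to 98667807, the Smc1 NOD libraries had 5571 and 2997 read pairs and the H3K27ac NOD libraries 1278 and 1813. On chromosome 11 around Sfi1 the Smc1 NOD libraries had 6596 and 9505 and the H3K27ac NOD libraries 2192 and 2349. On chromosome 17 at Rn18s-rs5 the H3K27ac NOD libraries had 436 and 484 and Smc1 NOD 2 had 935, with none listed in Smc1 NOD 1. The F1 library had 12281 read pairs at the 3 loci on the NOD genome and 0 on the BL6 genome, so mapping to the NOD genome may account for them, and a strain difference in these sequences stays open and untested.

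Of the 17 genes raised in Smc1 NOD libraries, 11 differed between genomes in F1. At 2 of these 11, the F1 library on the BL6 genome exceeded both BL6 libraries. Those 11 were picked by that same F1 ratio, and 9 of the 17 genes had no F1 read pairs on the BL6 genome. At those 9 genes the same F1 library had read pairs on the NOD genome, so what was listed there depended on the mapping genome. Of the 2 genes, Tmem267 had 613 CPM in F1 on the BL6 genome against at most 79.5 in BL6. At 1600014C10Rik these values were 11.4 and 10.6. Because the 11 were picked by the F1 ratio, the count of 2 could not test mapping to the NOD genome, which stays open for the 11. At the other 6 (Klra1, Klra4, Zfp988, Mrgpra3, Ifi203 and Gm42346) the F1 library on the BL6 genome exceeded both BL6 libraries at 6 of 6. It had 414 CPM against at most 4.41 at Klra1 and 159 against at most 23.4 at Mrgpra3. With 1 F1 library, mapping to the NOD genome stays open for these 6 too. For piled-up reads of repeated copies, the written limit was a median ratio of 3 or more. NOD anchors held a median of 4.70 times the library's median reads at the 11 genes, above it, and 2.17 times at the 6, below it. Their median absolute deviations, scaled to match the SD of normal values, were 3.41 and 1.14. These describe spread between genes, which the written limit did not include. Single genes lay on both sides of 3, from 1.24 to 17.2 at the 11 and from 1.09 to 10.1 at the 6. Piled-up reads therefore stay open for both sets. A strain difference in sequence, copy number or contact was not tested and stays open.

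The H3K27ac libraries resembled each other by replicate number and not by strain. Library depth was argued against, since NOD 2 correlated better with the deeper BL6 2 than with BL6 1, which is nearer in depth, by 0.458. Uneven chromosome representation was argued against as the whole cause, since same-number pairs exceeded same-strain pairs by at least 0.260 after each chromosome was centred. Swapped strain labels of 2 libraries stay open: both NOD libraries exceeded both BL6 libraries at 6 of the 6 genes that did not differ between genomes in F1, but that order argues against a swap only if mapping to the NOD genome is not its cause, which 1 F1 library leaves open. A preparation batch shared by libraries of 1 number stays open, because the labels give no batch, and no biological explanation was tested.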

How the results depend on the processing

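Normalization within each chromosome, whole gene spans, 25 kb bins in place of genes, at least 3 read pairs, a q-value up to 0.01 and, for lists, leaving out each library or the genes that differ between genomes in F1 were chosen after seeing the data. The planned limits of an FDR under 0.05 and of at least 2 read pairs were not run, because every listed interaction already met them. Leaving a library out left 1 library in its group, which was assumed to vary like the others. The cause of each shift below was not tested, except where fewer features or libraries entered by construction.

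For Smc1 genes (17 in the main result) the count was 55 with DESeq2, 0 with 2 kb and 30 with 10 kb windows, 6 with spans of 20 kb to 1 Mb, 8 with anchors in bins held by every library, 3 without genes that differ between genomes in F1, 0 in the joint fit, and 0 to 601 when leaving out a library. It was 27 with normalization within each chromosome, 6 with that and the replicate block, 34 with whole gene spans, 5 with at least 3 read pairs, 0 with a q-value up to 0.01, and 46 with 25 kb bins. In the alternatives on genes, the 17 genes kept a positive fold change wherever they were tested. Of the 17, 16 were called by DESeq2, 6 with spans of 20 kb to 1 Mb, and 0 with 2 kb windows, in the joint fit, with a q-value up to 0.01 or without either BL6 library. For H3K27ac genes (0) it was 24 with DESeq2, 8 with no filter, 18 with the replicate block and chromosome normalization together, and 0 to 16 when leaving out a library. For H3K27ac against Smc1 (0) it was 4 with DESeq2 and 0 to 3848 when leaving out a library. The interaction count by edgeR, with 323 genes at an unadjusted p under 0.05 in the main result, was 0 in all 12 alternatives.

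For Smc1 bin pairs (0) the count was 143 with DESeq2 and 0 to 61 when leaving out a library. For H3K27ac bin pairs (10) it was 29 with 10 kb and 0 with 50 kb bins, 24 with DESeq2 size factors (21 up, 3 down), 25 with DESeq2, and 0 to 23 when leaving out a library. Lists passing went from 2 to 0 in Smc1 with an estimated correlation and to 0 with 1 gene per 100 kb, and from 1 to 0 in H3K27ac with an estimated correlation. When leaving out a library they ranged from 1 to 5 in Smc1 and from 0 to 1 in H3K27ac. The F1 share of 4.52% was 2.20% with 10 kb windows, 5.96% with a minimum of 20 read pairs and 10.2% with at least 3 read pairs.

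The replicate numbers were shared only as numbers, with 2 pairs. For the Smc1 NOD libraries the names of the deposited tables carry other technical replicate numbers than the sample titles, which were used, so the Smc1 pairing is uncertain. Deviations of same-numbered libraries correlated by 0.186 in Smc1 and 0.483 in H3K27ac. With the replicate block the counts were 24 for Smc1 genes, 5 for H3K27ac genes, 15 for Smc1 bin pairs, 21 for H3K27ac bin pairs and 0 for H3K27ac against Smc1, with 2 and 1 lists passing.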

Other observations

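The following Ly49, other strain-polymorphic and MHC region genes were chosen after their values were seen. Values of Ly49 genes lay on both sides in Smc1. Klra7 and Klra9, which missed the threshold over all genes in Smc1 (edgeR adjusted p = 0.0566 and 0.0608), had 193 ± 122 and 216 ± 185 CPM in NOD against 5.94 ± 5.12 and no listed interaction in BL6. Errors of these Smc1 values are the SD of 2 technical libraries of 1 biological replicate per strain. Klra6 had 17.2 ± 1.46 CPM in BL6 and no listed interaction in NOD (edgeR adjusted p = 1.00). Other members of the strain-polymorphic list with higher means in NOD included Ifi202b (155 ± 110 against 12.3 ± 10.9 CPM), Ly6a (121 ± 65.2 against 28.2 ± 9.16) and Raet1e (47.7 ± 22.5 against 2.03 ± 0.406). Of the 54 tested members, 17 had negative fold changes.

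Among MHC region genes in Smc1, H2-Eb1 had 97.9 ± 2.81 CPM in BL6 and 36.4 ± 4.14 in NOD, and H2-Aa 74.1 ± 16.3 and 32.6 ± 1.24, neither passing over all genes (edgeR adjusted p = 1.00). Both encode chains of class II molecules, whose haplotype differs between these strains. Of the 30 tested MHC region genes, 19 had negative and 11 positive fold changes in Smc1.

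Smc1 NOD 1 and H3K27ac NOD 1 listed shorter contacts than the other libraries, with a median span of 562 kb and 543 kb against 690 kb to 807 kb elsewhere.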
